A study of Homo sapiens with 3 samples.

How the data were processed

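Total RNA of the HfSC MASC cells was extracted with Trizol and a column kit and made into libraries with a stranded Illumina total RNA kit, per the labels' protocols. Reads were processed with TopHat, Cufflinks and Cuffdiff on the hg19 genome, per the submitters' processing notes. Tool versions, the gene annotation, the counting of strand and the handling of reads that match several places are not given in the sources used here. Each of the 3 libraries had 1 table of genes with the values the authors deposited, in FPKM (fragments scaled by transcript length and library size) with an interval and a status per row, per the file headers. FPKM is already divided by length and library size by the authors, so levels of different genes and libraries can be set side by side, while a count test cannot be made. A share of rows were loci assembled within each library (18983, 19608 and 18947 rows in replicates 2, 3 and 4) which can join neighbouring genes: 1025, 910 and 920 rows named more than 1 gene, and each gene of such a row was given the value of the row.

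The tables held 32892, 31500 and 30831 rows. Replicate 2 had 26257 gene names, replicates 3 and 4 had 23615 and 23616, with 3781 names only in replicate 2 and 1140 only in replicates 3 and 4, and the rows of status LOWDATA numbered 0, 123 and 115. Older symbols were matched to current ones with a table of human gene names and the RefSeq gene table in the reference folder, by which 25703 of 27397 names matched a current symbol. Coordinates are those of the deposited tables on hg19, with starts counted from 1, and are those of the highest row of a gene in any library, on the primary chromosomes where there is one. The reference (GENCODE version 29 on another build) was used only for symbols, gene types, GC content and transcript length. Rows of the same symbol were summed within a library, rows on haplotype and unplaced contigs included (1261, 1191 and 1191 rows, at 0 FPKM wherever they named a gene). Leaving out 8 genes with a failed estimate gave 22924 genes listed in all 3 libraries, of which 18604 were protein-coding, 2343 had a shared row in at least 1 library and 5976 were at 0 in all 3. Rows without a gene name (6221, 7478 and 6817) and the row of the mitochondrial genome were not used in the tests. The deposited sums of FPKM were 14573643, 729718 and 661353, of which rows under 200 bp held 96.8%, 35.8% and 29.6%. In replicate 2 most of the sum was 1 row of 89 bp, MIR6723, at 13856200 FPKM. The sums over tested genes were 519213, 507882 and 510597. Genes with near-identical copies elsewhere in the genome, such as the ribosomal proteins, EEF1A1, FTH1, actins and the HLA genes, and overlapping or antisense genes, have uncertain values where reads could be shared.

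Main tests were fixed before the data were examined. Each gene was tested with limma (version 3.58.1, R 4.3.3), a moderated 1-sample test with a mean-dependent trend of log2(FPKM + 1) against the value at 1 FPKM, 2-sided, with Benjamini-Hochberg adjustment over the 22924 genes and an adjusted p below 0.05 for a call of above or below. The pseudocount of 1 understates differences of low genes. The lowest mean called above was 1.17 FPKM and the highest called below was 0.891 FPKM. The median of each of 35 gene lists was compared with 100000 random lists of protein-coding genes of the same size (2-sided permutation test, adjusted over the lists), and the stromal matrix list with each of 15 lineage lists by permuting list membership. The adjustment over the list alone gave the same counts above and below in 34 of the 35 lists, all but the osteogenic list. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6 was used.

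The lists were MSC surface markers, MSC exclusion markers, pluripotency, reprogramming factors, stromal matrix, papillary and reticular dermal fibroblast, smooth muscle and pericyte, skeletal muscle, cardiac muscle, adipogenic, osteogenic, chondrogenic, neural crest and neural progenitor, neuron, glia, endothelial, keratinocyte, melanocyte, immune, endoderm and liver, HOX, proliferation, cell cycle inhibitors, senescence secretory, trophic factors, immunomodulatory, HLA class I, HLA class II, cholesterol synthesis, immediate early, TGF-beta response, replication histones, abundant noncoding RNA and housekeeping. Named genes were the 10 highest, the 25 highest without mitochondrial, ribosomal, histone and noncoding genes, a fixed set of stem cell and cell cycle markers, the 3 highest of each list with up to 2 members called opposite to most of it, each HOX gene called above, and the 10 with the largest range between libraries among genes of mean FPKM of at least 10. Some genes that these rules name are not reported here. Genes of the Y chromosome and genes of X inactivation were never named.

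The tests were tested on simulated data with the real genes. Of 50 genes simulated at each level, 96.0% at 8 FPKM, 92.0% at 2 FPKM, 88.0% at 0.5 FPKM and 100% at 0.125 FPKM were called on their side. Over all genes 14 of 21528 calls fell on the wrong side. The other genes kept their real means, many of them at 0, so this count says little about genes near the level. Random lists passed the list test in 11 of 200 cases and lists raised by 3 (log2) in 35 of 50, so that a list can stand apart by this much and not be called. All of these lists had the same size, were compared with all tested genes and were judged by a p without adjustment. Lists set low were not simulated, so how often a list near 0 would be called is unknown. Random pairs of lists passed the stromal test in 6 of 200 cases and pairs set apart by 4 (log2) in 48 of 50. Alternatives were detection levels of 0.5 and 5 FPKM, a pseudocount of 0.1, rescaling to TPM or by median-of-ratios factors, a filter of 0.1 FPKM, limma without a trend, the highest row in place of the sum, the mean of a list, other backgrounds and leaving out each library.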

Results

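Multipotent adult stem cells grown from human foreskin, which the submitters named HfSC MASC, were profiled by RNA sequencing at passage 20. The cells were grown in medium with 5% horse serum to 80% confluence, were kept without serum for the last 24 hours and received no treatment. The data were 1 group of 3 libraries, called replicates 2, 3 and 4 after the sample titles, without a control group. The stated purpose was to characterise the transcriptome of these cells, so each gene was compared with a fixed detection level of 1 FPKM. Gene lists were compared with other genes, the stromal matrix genes were compared with lineage genes, and the libraries were compared with each other. The labels describe the replicates as both biological and technical and do not say whether they came from separate cultures or donors. The limma p-values therefore measure only the spread between these libraries, which may be technical. The p-values of the list tests and of the counts of genes come from comparing genes with genes and measure no spread between libraries.

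Values are in FPKM, fragments scaled by transcript length and library size, given as mean ± SD over the 3 libraries (n = 3). Differences from the detection level are on the log2(FPKM + 1) scale with their standard errors. A gene that was listed at 0 in any library is given by its values in replicates 2, 3 and 4. Genes with a failed estimate were left out, but a 0 in these tables can stand beside 10 FPKM or more in another library. FPKM values hold no fragment totals, so the absolute depth is unknown and no counting error is given. The step that 1 fragment makes in genes of low level put the depth of replicate 3 at 1.04 times that of replicate 2, from 227 of 1057 low genes that shared this ratio within 1%. It put replicate 4 at 0.964 times replicate 2, from 247 of 1059 low genes.

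Among the genes tested, the 10 of the highest level included genes of translation, iron storage, matrix and the cytoskeleton. EEF1A1, the translation elongation factor, was highest at 7571 ± 389 FPKM. Next were the ferritin chains FTH1 (4766 ± 1626) and FTL (4693 ± 592), the matrix proteoglycan LUM (4207 ± 609.8) and the ribosomal protein RPL41 (3722 ± 208). The membrane-binding protein ANXA2 (3714 ± 1154), the secreted IGF-binding protein IGFBP7 (3431 ± 125), the actin-binding thymosins TMSB4X (3274 ± 28.2) and TMSB10 (3081 ± 232) and the HLA class I light chain B2M (3246 ± 658) completed the 10 highest. Further genes above 1000 FPKM included VIM (2705 ± 886), the intermediate filament of mesenchymal cells, the collagen COL1A2 (1735 ± 78.9), the matrix glycoproteins FN1 (1824 ± 199.6), SPARC (1710.2 ± 252) and THBS1 (1212 ± 162), and the annexin ANXA1 (1805 ± 144). The calcium-binding proteins S100A6 (1894 ± 53.5) and S100A11 (1415 ± 84.8), the actins ACTB (1345 ± 188) and ACTG1 (1228 ± 118), the actin regulator PFN1 (1297 ± 332), the myosin light chain MYL6 (2411 ± 176) and the growth-associated TPT1 (1795 ± 563) also lay above 1000 FPKM. Of these, TPT1 shared a row with another gene in at least 1 library. The 10 highest genes held 8.14% ± 0.293 of the FPKM of the tested genes, and the 100 highest held 30.1% ± 0.584.

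Of 22924 genes tested, 10893 (47.5%) were called above the detection level, 10355 (45.2%) were called below it and 1676 were not called. Among the 18604 protein-coding genes, 10267 were called above, 7060 below and 1277 were not called. A detection level of 5 FPKM moved 16 of the 161 named genes to the other side and a level of 0.5 FPKM moved 3. In each library between 11773 and 11887 genes reached 1 FPKM, and 11308 reached it in all 3. The 14 housekeeping genes were all called above the level (14 and 0 above and below adjusted over the list alone), with ACTB and GAPDH (2624 ± 295 FPKM) among the highest. The median of the list was 8.32 ± 0.04 (log2) against 1.96 for random lists of protein-coding genes (permutation test, adjusted p = 0.00014, above in 3 of 3 libraries). Every list test below is such a 2-sided permutation test with 100000 random lists, adjusted over 35 lists, and its genes are not independent replicates. List medians are given as the mean ± SD of the medians in the 3 libraries. The median tested is that of the gene means over the libraries, which can differ (7.83 against 7.89 for the stromal matrix list). By that test 7 lists lay above other protein-coding genes, 2 lay below and 26 were not separated from them, while 18 lay below when the background held only genes of at least 0.1 FPKM in any library and 12 with the mean of the list in place of the median. The background of at least 0.1 FPKM leaves out silent genes while the lists keep theirs. An ordinary list with silent members would therefore also lie lower against it. The smallest p that the permutations can give was 2e-05.

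Genes of surface proteins that are used to define or describe mesenchymal stromal cells were mostly called above the level, as RNA. THY1 (hg19 chromosome 11, 119288655 to 119294246) was at 429 ± 60.2 FPKM, which was 7.74 ± 0.11 above the level (limma, adjusted p = 3.94e-05, 3 of 3 libraries). The ecto-nucleotidase NT5E was at 50.5 ± 10.9 FPKM and the TGF-beta co-receptor ENG at 20.9995 ± 4.15 FPKM. The highest members were the tetraspanin CD63 (1538 ± 93.8 FPKM) and the integrin ITGB1 (1155 ± 120.3 FPKM). In all, 12 of 14 surface markers were called above the level and 2 below (12 and 2 adjusted over the list alone). The members called below were VCAM1, an adhesion molecule, at 0.0533 ± 0.0344 FPKM, and the neurotrophin receptor NGFR, at 0.0566, 0 and 0.0293 FPKM. The list median was 6.06 ± 0.09 (log2), above that of random lists (permutation adjusted p = 0.00014).

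Markers whose absence is used in the same definition were low. All 8 were called below the level (0 and 8 above and below adjusted over the list alone), among them the stem cell and endothelial antigen CD34 (0.456 ± 0.0774 FPKM), the leukocyte antigen PTPRC (0.235 ± 0.0606 FPKM) and the monocyte antigen CD14 (0.202 ± 0.1247 FPKM). The class II chain HLA-DRA was listed at 0.0415, 0 and 0 FPKM. The list median of 0.07 ± 0.02 (log2) was not separated from random lists (permutation adjusted p = 0.158), and it was called below them with background genes of at least 0.1 FPKM (difference -3.06), with the mean of the list (-2.10) and with a pseudocount of 0.1 and the mean (-3.46). With 8 genes near 0 the median still lay at the 5.19th percentile of random lists, so the main test had little room to call this list. CD34 was not called with a detection level of 0.5 FPKM (difference -0.04, log2) or after rescaling to TPM (-0.08).

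**Figure D1:**
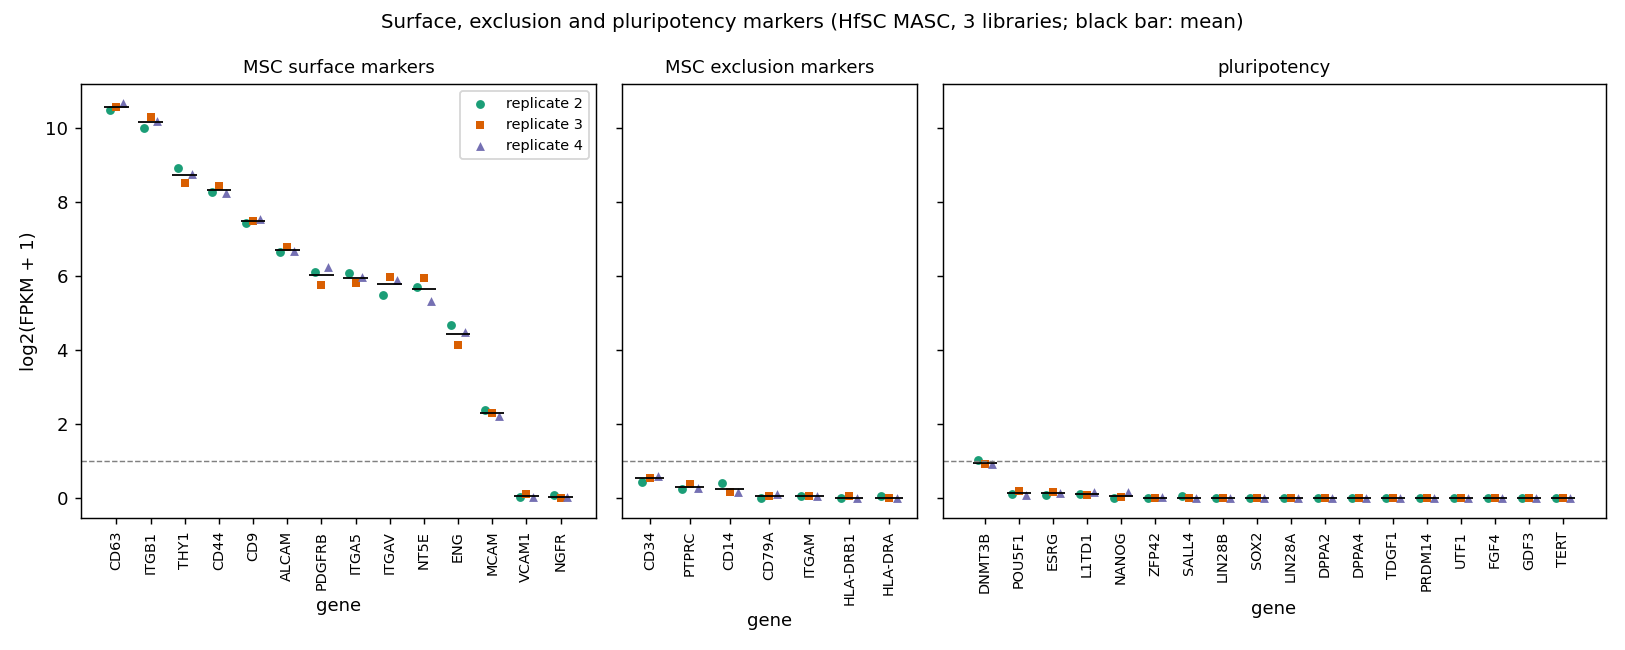
Each point is log2(FPKM + 1) of a gene (x axis) in 1 library, with colour and shape giving replicates 2, 3 and 4, black bars the mean, and the dashed line the detection level of 1 FPKM. Of the surface markers 12 of 14 lie above the line, while the exclusion markers shown lie below it and 17 of 18 pluripotency genes were called below it.

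Pluripotency genes were near the floor. Of 18 genes, 17 were called below the level, 0 above and 1 was not called (0 and 17 above and below adjusted over the list alone). Of the 18, 10 were listed at 0 in all 3 libraries, so the list median rests on zeros. A 0 in these tables need not mean that no RNA was present. The core factors POU5F1 (0.109 ± 0.0428 FPKM) and NANOG (0.0482 ± 0.0626 FPKM) were below the level, and SOX2 and LIN28A were listed at 0 in all 3 libraries. The noncoding RNA ESRG was at 0.0990 ± 0.0378 FPKM. DNMT3B, a DNA methyltransferase, was the gene not called, at 0.959 ± 0.0945 FPKM, and it was called above when the level was 0.5 FPKM (difference 0.38, log2) and after rescaling to TPM (0.52). The list median was 0.00 ± 0.00 (log2) against 1.97 for random lists, 1 of the 2 lists below the background (permutation adjusted p = 0.0053, below in 3 of 3 libraries). This call ended with all genes as background, where the difference was -1.24. Of the 4 reprogramming factors, KLF4 (6.35 ± 0.925 FPKM) and MYC (7.31 ± 2.70 FPKM) were called above the level and POU5F1 and SOX2 below (2 and 2 adjusted over the list alone). The list median of 1.44 ± 0.07 (log2) was not separated from random lists (permutation adjusted p = 0.798).

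Genes of the stromal matrix had the highest median of the cell type lists. All 30 members were called above the level (30 and 0 above and below adjusted over the list alone), led by LUM (hg19 chromosome 12, 91497232 to 91505618), VIM and the galectin LGALS1 (2360.1 ± 551 FPKM), and S100A4 (2135 ± 29.5 FPKM) shared a row with another gene. The list median was 7.89 ± 0.15 (log2) against 1.98 for random lists (permutation adjusted p = 0.00014). The median of the matrix genes exceeded that of each of 15 lineage lists, and the difference passed the permutation of list membership in all 15 (2-sided, adjusted over 15 lists, genes not independent replicates). The smallest difference was against smooth muscle and pericyte genes, 3.98 ± 0.03 log2 over the libraries (permutation adjusted p = 0.00036, 3 of 3 libraries). It was 7.19 ± 0.24 against osteogenic, 7.61 ± 0.13 against chondrogenic, 7.70 ± 0.20 against neuron and 7.78 ± 0.11 against adipogenic genes, and between 7.83 and 7.89 against the other 10 lists.

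**Figure D2:**
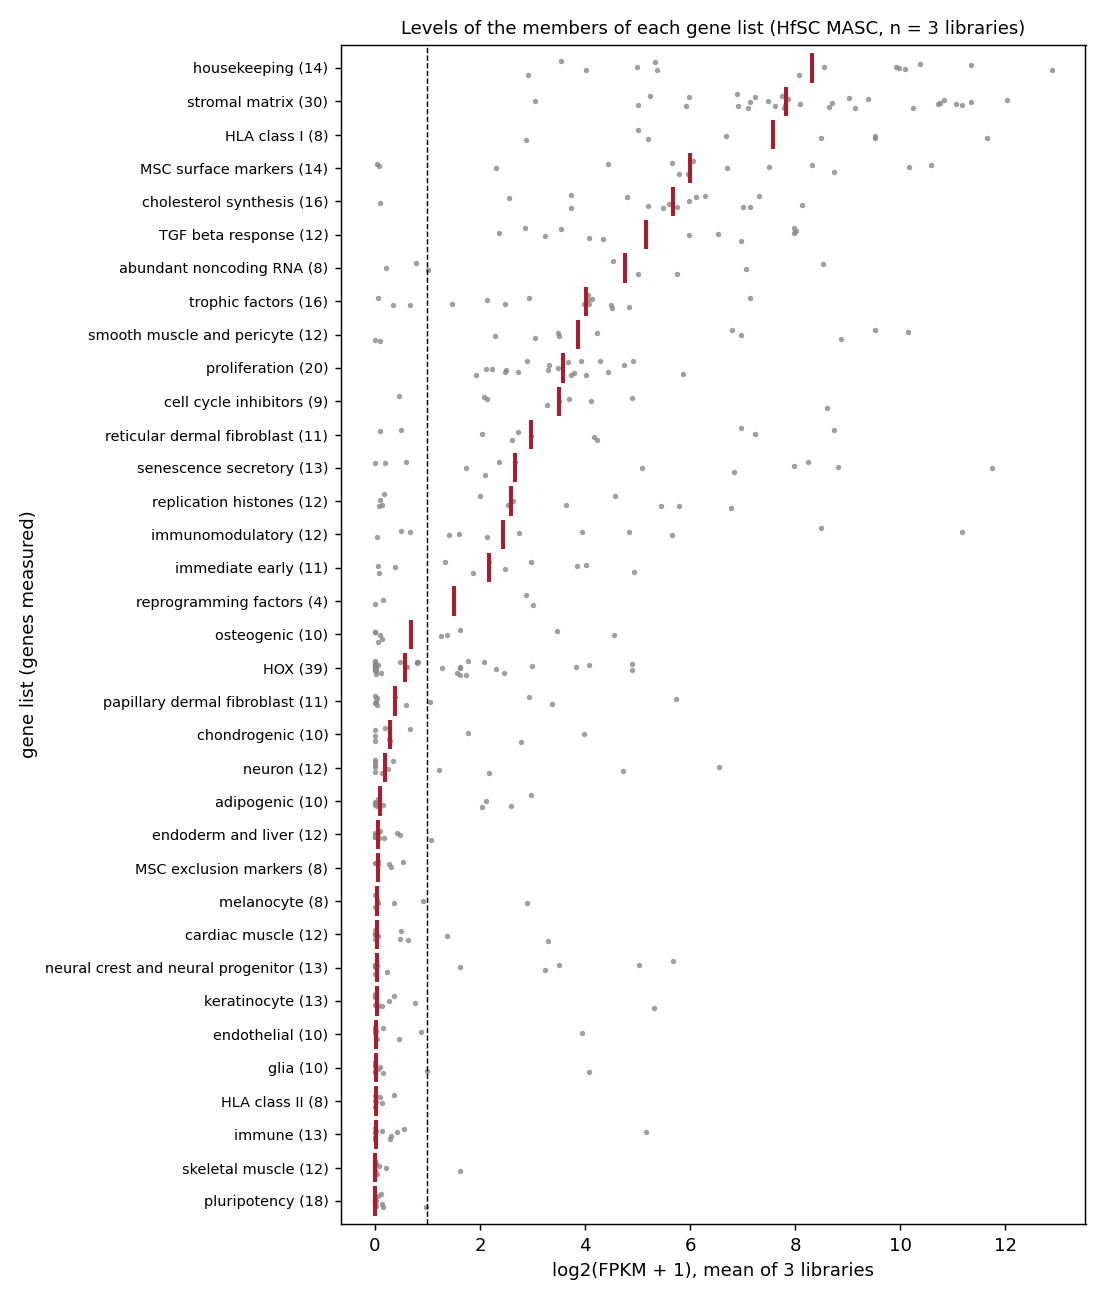
Each grey point is the mean log2(FPKM + 1) of 1 gene over the 3 libraries (x axis), grouped by gene list (y axis, ordered by median, with the number of genes measured), red bars are list medians and the dashed line is the detection level of 1 FPKM. The stromal matrix list has a median of 7.83 and lies beside the housekeeping list, while the medians of the skeletal muscle and pluripotency lists lie at the left edge.

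Genes that mark the layers of the dermis were split. Of the reticular, deep-layer markers 9 of 11 were called above the level and 2 below (9 and 2 adjusted over the list alone). THY1, elastin ELN (154 ± 40.5 FPKM) and the smooth muscle actin ACTA2 (126 ± 21.2 FPKM, on a shared row) were highest. These genes also belong to the MSC surface, stromal matrix and smooth muscle lists, so the reticular counts partly repeat those lists. FMO1 was at 0.406 ± 0.0728 FPKM and SLPI at 0, 0.208 and 0 FPKM. Of the papillary, upper-layer markers 3 of 11 were called above and 7 below (3 and 7 adjusted over the list alone). Those above were the Wnt inhibitor APCDD1 (52.3 ± 5.08 FPKM), the small heat shock protein HSPB3 (9.40 ± 1.10 FPKM) and the anchoring fibril collagen COL7A1 (6.97 ± 2.76 FPKM, on a shared row). Neither list was separated from random lists, with medians of 2.98 ± 0.12 and 0.38 ± 0.28 (log2; permutation adjusted p = 0.458 and 0.366), and the difference between the lists was not tested. The reticular list was called above with a pseudocount of 0.1 and the mean (difference 2.32), and the papillary list below with background genes of at least 0.1 FPKM (-2.76). COL7A1 was not called without replicate 3 (difference 1.96, log2). FMO1 was not called at a detection level of 0.5 FPKM (-0.09) or after rescaling to TPM (-0.16).

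Single contractile genes stood high within a smooth muscle and pericyte list that was not separated from random lists. TAGLN (1131 ± 36.6 FPKM, on a shared row), the myosin light chain MYL9 (736 ± 109 FPKM) and the actin-binding CALD1 (469.6 ± 3.03 FPKM) led the smooth muscle and pericyte list. In it 10 of 12 were called above and 2 below (10 and 2 adjusted over the list alone). The smooth muscle myosin MYH11 was listed at 0 in all 3 libraries and desmin, DES, was at 0.0740 ± 0.0154 FPKM. The list median of 3.91 ± 0.14 (log2) did not pass the permutation test (adjusted p = 0.103), and it was called above with the mean of the list (difference 2.64) and with a pseudocount of 0.1 and the mean (3.33). Of the skeletal muscle genes 11 of 12 were called below and 1 above (1 and 11 above and below adjusted over the list alone). The gene above was the developmental factor PAX3 (2.09 ± 0.189 FPKM), and the myosins MYH2 (0.0607 ± 0.0102 FPKM) and MYH3 (0.159 ± 0.0525 FPKM) were the next. The skeletal muscle list lay below random lists (median 0.00 ± 0.00, permutation adjusted p = 0.0286, below in 3 of 3 libraries), a call that ended with all genes as background (difference -1.25). Of its 12 genes 6 were listed at 0 in all 3 libraries, so its median rests largely on zeros, which need not mean that no RNA was present. In the cardiac list the limb and heart factor TBX5 (8.84 ± 0.744 FPKM) was called above, 9 genes were called below, and the actin ACTC1 (1.61 ± 0.367 FPKM) and the troponin TNNT2 (0.569 ± 0.265 FPKM) were not called (1 and 9 above and below adjusted over the list alone). Its median of 0.04 ± 0.07 (log2) was not separated from random lists (permutation adjusted p = 0.103), and it was called below them without replicate 4 (difference -1.96), with the mean of the list (-1.74), with a pseudocount of 0.1 and the mean (-2.80) and with background genes of at least 0.1 FPKM (-3.08). ACTC1 was called above at a detection level of 0.5 FPKM (difference 0.79, log2), after rescaling to TPM (1.03), with genes below 0.1 FPKM in every library left out (0.37) and with genes at 0 in 1 or 2 libraries and at least 1 FPKM in another left out (0.37). TNNT2 was called below with genes below 0.1 FPKM in every library left out (-0.36).

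Genes of the mesenchymal lineages that such cells are tested for were present in part. In the adipogenic list 4 of 10 genes were called above and 6 below (4 and 6 adjusted over the list alone), the highest being the fatty acid transporter CD36 (6.88 ± 0.643 FPKM), the lipid enzyme AGPAT2 (5.06 ± 1.09 FPKM) and the fatty acid binding protein FABP4 (3.34 ± 0.213 FPKM). The osteogenic list had 4 genes above, 5 below and 1 not called (5 and 5 above and below adjusted over the list alone). Among its members BGLAP (23.2 ± 7.48 FPKM), which shared a row, the bone matrix protein SPP1 (10.1 ± 1.65 FPKM) and the homeobox gene MSX2 (2.09 ± 0.3203 FPKM) were highest. In the chondrogenic list 3 genes were called above and 7 below (3 and 7 adjusted over the list alone). Above were the cartilage matrix proteins COMP (15.3 ± 4.86 FPKM) and MATN3 (5.84 ± 0.470 FPKM) and the factor SOX6 (2.42 ± 0.186 FPKM, on a shared row). None of these lists was separated from random lists, with medians of 0.10 ± 0.04, 0.69 ± 0.09 and 0.28 ± 0.04 (log2; permutation adjusted p = 0.162, 0.433 and 0.263), but with background genes of at least 0.1 FPKM the adipogenic, osteogenic and chondrogenic lists were called below (differences of -3.03, -2.43 and -2.84). MSX2 was not called without replicate 3 (difference 0.56, log2) or without replicate 4 (0.59).

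Single neural genes stood high within lists that were otherwise low. STMN2, a microtubule regulator of neurons (hg19 chromosome 8, 80523049 to 80578410), was at 92.9 ± 1.07 FPKM, or 5.55 ± 0.01 above the level (limma, adjusted p = 8e-07, 3 of 3 libraries). The tubulin TUBB3 was at 25.6 ± 4.57 FPKM and the synaptic SNAP25 at 3.53 ± 0.139 FPKM. Of the neuron genes 4 of 12 were called above and 8 below (4 and 8 adjusted over the list alone). In the neural crest and progenitor list 5 of 13 were above and 8 below (5 and 8 adjusted over the list alone). The highest were nestin, NES (50.3 ± 3.31 FPKM), and the mesenchymal transcription factors SNAI2 (31.8 ± 2.01 FPKM) and TWIST1 (10.5 ± 1.98 FPKM). The glial list had 1 gene above, CNP (16.0 ± 1.90 FPKM), 8 below, including GFAP (0.115 ± 0.0234 FPKM), and MBP (0.990 ± 0.0315 FPKM) not called (1 and 8 above and below adjusted over the list alone). In the melanocyte list the transcription factor MITF (6.44 ± 0.451 FPKM) was above, 6 genes were below, including PMEL (0.283 ± 0.0454 FPKM), and MLANA (0.903 ± 0.265 FPKM) was not called (1 and 6 above and below adjusted over the list alone). The list medians were 0.19 ± 0.05, 0.06 ± 0.02, 0.03 ± 0.01 and 0.05 ± 0.03 (log2), and none was separated from random lists (permutation adjusted p = 0.194, 0.105, 0.103 and 0.149). All 4 were called below background genes of at least 0.1 FPKM (differences of -2.93, -3.10, -3.10 and -3.09), and the glial and melanocyte lists were also called below with the mean of the list (-1.73 and -1.71) and with a pseudocount of 0.1 and the mean (-3.03 and -2.77). MBP was called above a level of 0.5 FPKM (difference 0.41, log2) and above 1 after rescaling to TPM (0.55).

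Markers of keratinocytes, endothelial cells, immune cells and endoderm were mostly low, with 1 gene called above in each of the first 3 lists. Other cell types that a skin culture could hold are described above, among them smooth muscle and pericytes, where most genes were called above. In the keratinocyte list KRT10, a keratin, was called above at 49.97 ± 45.2 FPKM, with 102, 27.1 and 20.8 FPKM in replicates 2, 3 and 4. There 11 of 13 genes were below, including EPCAM (0.286 ± 0.0527 FPKM), and KRT15 (0.714 ± 0.224 FPKM, on a shared row) was not called (1 and 11 above and below adjusted over the list alone). In the endothelial list the VEGF receptor FLT1 was called above at 14.3 ± 0.413 FPKM. There 8 of 10 genes were below, including TEK (0.375 ± 0.0530 FPKM), and EMCN (0.844 ± 0.169 FPKM) was not called (1 and 8 above and below adjusted over the list alone). In the immune list the lysosomal protein CD68 was called above at 35.0 ± 5.80 FPKM. There 12 of 13 genes were below, including LAPTM5 (0.334 ± 0.0701 FPKM) and the mast cell protease CPA3 (0.470 ± 0.225 FPKM) (1 and 12 above and below adjusted over the list alone). The endoderm and liver list had 0 genes above, 10 below, including GATA6 (0.335 ± 0.0365 FPKM), and 2 not called (0 and 10 above and below adjusted over the list alone). Those not called were AFP (0.416 ± 0.339 FPKM) and APOA1, which shared a row and was listed at 0, 7.23 and 0.131 FPKM. The medians of the keratinocyte, endothelial, immune and endoderm lists were 0.03 ± 0.01, 0.03 ± 0.03, 0.01 ± 0.02 and 0.03 ± 0.02 (log2), not separated from random lists (permutation adjusted p = 0.103, 0.103, 0.0612 and 0.117). These 4 lists were called below with background genes of at least 0.1 FPKM (differences of -3.10, -3.10, -3.12 and -3.06), with the mean of the list (-1.74, -1.71, -1.75 and -2.08) and with a pseudocount of 0.1 and the mean (-3.03, -2.90, -3.01 and -3.54). KRT10 was not called without replicate 3 (difference 4.57, log2), and CPA3 was not called without replicate 2 (-0.46) or replicate 4 (-0.35), at a detection level of 0.5 FPKM (-0.04), after rescaling to TPM (-0.09) or with a pseudocount of 0.1 (-1.03). AFP was called below without replicate 2 (-0.71) and with genes below 0.1 FPKM in every library left out (-0.52). So were EMCN (-0.19) and APOA1 (-0.91) without replicate 3, while EMCN was called above a level of 0.5 FPKM (0.29) and after rescaling to TPM (0.40).

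HOX genes, which mark position along the body axis, were expressed from restricted parts of the clusters. In the HOXA cluster HOXA9 and HOXA10 lay on 1 shared row (hg19 chromosome 7, 27202057 to 27219880) at 28.6 ± 0.771 FPKM, so the level of either gene alone cannot be given. HOXA11 was at 16.0 ± 0.705 FPKM and HOXA13 (hg19 chromosome 7, 27232865 to 27239737) at 13.3 ± 1.21 FPKM, while HOXA7 (2.32 ± 0.0629 FPKM) was lower. In the HOXC cluster HOXC10 was at 7.01 ± 0.830 FPKM, HOXC11 at 3.95 ± 0.763 FPKM and the shared row of HOXC4, HOXC5 and HOXC6 at 2.11 ± 0.402 FPKM. HOXD10 (4.59 ± 1.18 FPKM, on a shared row), HOXD8 (2.42 ± 0.246 FPKM) and HOXD9 (1.96 ± 0.328 FPKM) were called above, and no HOXB gene was. Of 39 HOX genes 14 were called above, 22 below and 3 were not called (14 and 22 above and below adjusted over the list alone). The list median of 0.53 ± 0.05 (log2) was not separated from random lists (permutation adjusted p = 0.15), and it was called below them with background genes of at least 0.1 FPKM (difference -2.56), with the mean of the list (-1.18) and with a pseudocount of 0.1 and the mean (-1.72). Without replicate 2 and without replicate 4, limma did not call the row of HOXC4, HOXC5 and HOXC6 (differences of 0.53 and 0.63, log2) or HOXD9 (0.62 and 0.59). At a detection level of 5 FPKM only HOXA9, HOXA10, HOXA11, HOXA13 and HOXC10 of these genes were called above it.

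**Figure D3:**
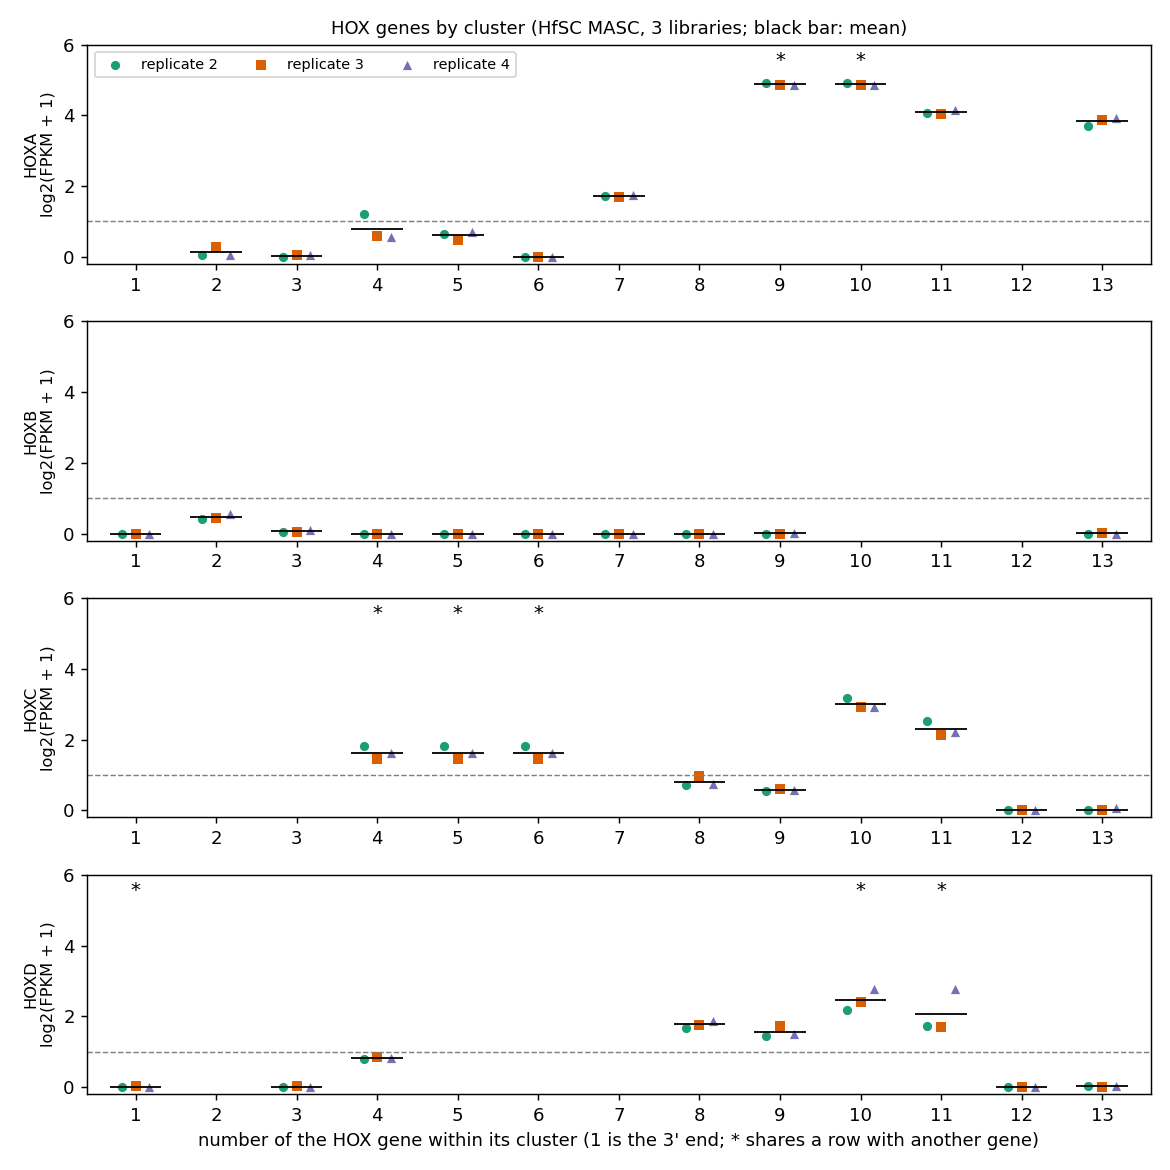
Each panel is 1 HOX cluster, the x axis is the number of the gene within it and the y axis log2(FPKM + 1), with points for replicates 2, 3 and 4, black bars for their mean, a dashed line at the detection level of 1 FPKM and asterisks over genes that share a row. The highest values are those of HOXA9 and HOXA10, followed by HOXA11 and HOXA13, and no HOXB gene reaches the line.

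Genes of cell division were all expressed, together with most inhibitors of the cell cycle. All 20 proliferation genes were called above the level (20 and 0 above and below adjusted over the list alone), among them the replication clamp PCNA (57.3 ± 6.22 FPKM), the mitotic cyclin CCNB1 (29.03 ± 2.72 FPKM), the thymidylate synthase TYMS (27.6 ± 11.95 FPKM) and the proliferation antigen MKI67 (4.67 ± 1.27 FPKM). Their median of 3.52 ± 0.29 (log2) against 1.98 for random lists did not pass the adjusted test (permutation adjusted p = 0.103), and it was called above with the mean of the list (difference 1.24), with a pseudocount of 0.1 and the mean (2.34) and with all genes as background (2.33). Of 9 inhibitors 8 were called above and 1 below (8 and 1 adjusted over the list alone). CDKN1A, an inhibitor of the G1 cyclin-dependent kinases, was at 389 ± 34.2 FPKM, 7.60 ± 0.07 above the level (limma, adjusted p = 1.64e-05, 3 of 3 libraries). RB1 was at 16.5 ± 3.63 FPKM and CDKN2A at 10.6 ± 2.16 FPKM, and CDKN1C was below at 0.379 ± 0.101 FPKM. The median of this list was 3.53 ± 0.26 (log2; permutation adjusted p = 0.263). CDKN1C was not called at a detection level of 0.5 FPKM (difference -0.12, log2) or after rescaling to TPM (-0.21). Between the libraries, 15 of the 20 proliferation genes were highest in replicate 3, 19 were higher in replicate 3 than in replicate 4 and 19 were higher in replicate 2 than in replicate 4.

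Single genes of secreted proteins stood high, while of the 4 lists below only the TGF-beta response list was separated from random lists. In the senescence secretory list IGFBP7, IGFBP3 (449.7 ± 59.6 FPKM) and the collagenase MMP1 (309 ± 73.2 FPKM) were highest and 10 of 13 genes were called above and 3 below (10 and 3 adjusted over the list alone). The interleukin IL1A was listed at 0 in all 3 libraries and IL1B was at 0.140 ± 0.0655 FPKM. Of the trophic factors 13 of 16 were above and 3 below (13 and 3 adjusted over the list alone). The chemokine CXCL12 was at 140.3 ± 17.9 FPKM, PDGFC at 27.8 ± 2.40 FPKM and FGF2 at 21.8 ± 1.77 FPKM, against 0.269 ± 0.164 FPKM for IGF1 and 0.0408 ± 0.0212 FPKM for IGF2, which shared a row. The TGF-beta response list had all 12 genes above (12 and 0 above and below adjusted over the list alone), including CCN2 (257 ± 6.79 FPKM) and TGFBI (252 ± 19.9 FPKM). Its median of 5.16 ± 0.11 (log2) lay above random lists (permutation adjusted p = 0.00338, 3 of 3 libraries). Of the immunomodulatory genes 8 of 12 were above, 2 below and 2 not called (8 and 2 above and below adjusted over the list alone). LGALS1 and NT5E were among the highest, while the tryptophan enzyme IDO1 was at 0.420 ± 0.209 FPKM and LGALS9 at 0.0323, 0.0310 and 0 FPKM. The medians of the senescence secretory, trophic and immunomodulatory lists were 2.66 ± 0.21, 3.94 ± 0.03 and 2.44 ± 0.08 (log2), not separated from random lists (permutation adjusted p = 0.612, 0.0561 and 0.723). The senescence secretory list was called above with the mean of the list (difference 2.21) and with a pseudocount of 0.1 and the mean (2.83), and the trophic list with all genes as background (2.77). IGF1 was not called without replicate 2 (difference -0.68, log2), and IDO1 was not called without replicate 2 (-0.47) or replicate 3 (-0.42). Neither was called at a detection level of 0.5 FPKM (-0.25 and -0.09) or after rescaling to TPM (-0.42 and -0.16).

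The antigen presentation genes of class I and class II were called on opposite sides of the level, and the difference between the lists was not tested. All 8 class I genes were called above the level (8 and 0 above and below adjusted over the list alone), with B2M highest and the shared row of HLA-B and HLA-C at 732 ± 67.8 FPKM. Their median of 7.58 ± 0.42 (log2) lay above random lists (permutation adjusted p = 0.00014), and without the genes on shared rows it did not pass (difference 3.22). All 8 class II genes were called below (0 and 8 above and below adjusted over the list alone), with HLA-DPB1 highest at 0.296 ± 0.109 FPKM and the invariant chain CD74 at 0.163, 0.117 and 0 FPKM and HLA-DPA1 at 0, 0.0569 and 0.158 FPKM. Their median of 0.01 ± 0.02 was not separated from random lists (permutation adjusted p = 0.103), and the list was called below them with background genes of at least 0.1 FPKM (difference -3.10), with the mean of the list (-2.18) and with a pseudocount of 0.1 and the mean (-3.87). HLA-DPB1 was not called at a detection level of 0.5 FPKM (difference -0.21, log2).

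Cholesterol synthesis genes were high after the period without serum, and no serum-fed culture was measured beside them. The farnesyl diphosphate synthase FDPS (279.8 ± 38.0 FPKM) and HMGCS1 (159 ± 13.5 FPKM), an early enzyme of the pathway, were highest. Of 16 genes 14 were called above, 1 below and 1 was not called (14 and 1 above and below adjusted over the list alone). Their median of 5.83 ± 0.05 (log2) lay above 1.96 for random lists (permutation adjusted p = 0.00014, 3 of 3 libraries). The gene not called was the squalene synthase FDFT1, named after its values were seen, which was listed at 0, 202 and 0 FPKM in replicates 2, 3 and 4. Of 11 immediate early genes 7 were above, 3 below and 1 was not called (7 and 3 above and below adjusted over the list alone). The highest were IER3 (29.9 ± 5.16 FPKM), the phosphatase DUSP1 (15.2 ± 0.257 FPKM) and JUN (13.3 ± 0.761 FPKM), and FOSB (0.0605 ± 0.0377 FPKM) and EGR3 (0.0366 ± 0.0348 FPKM) were lowest. The median of 2.18 ± 0.14 (log2) was not separated from random lists (permutation adjusted p = 0.878), lying 0.19 above them by the median and -0.07 from them by the mean.

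The 3 libraries were close to each other. Across the 22924 genes, which are not independent replicates, Pearson's r of log2(FPKM + 1) was 0.972 between replicates 2 and 3, 0.968 between replicates 2 and 4 and 0.969 between replicates 3 and 4, and Spearman's rho was 0.958, 0.956 and 0.957. Among genes of at least 1 FPKM in both libraries the median absolute difference of log2(FPKM + 1) was 0.16, 0.11 and 0.15 for these pairs. By FPKM + 1, 372, 340 and 300 genes differed by more than 2-fold. The added 1 shrinks the differences of genes near 1 FPKM, so more genes differ by this much in FPKM itself. The median coefficient of variation was 10.3% over genes of mean FPKM of at least 1. It was 8.89% without replicate 2, 6.75% without replicate 3 and 9.31% without replicate 4. These values rest on 2 libraries each and compare with each other rather than with 10.3%. Replicate 2 carried newer gene names than replicates 3 and 4, so the tables were not all made with the same gene annotation. Of rows of at least 1 FPKM, 0.0133% lay outside their own deposited interval in replicate 2 against 5.35% and 4.87% in replicates 3 and 4, and only replicate 2 had no rows of status LOWDATA. The values of replicate 2 may therefore come from another version or setting of the estimation, and with 1 library against 2 neither this nor the annotation can be told apart from the library.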

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

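The test of short rows, the comparisons by kind of gene and of each gene with itself and the corrections of replicate 4 were chosen after the patterns were seen, and the other tests were set out before their results. No biological explanation was tested for any of these patterns, since the design has 1 group.

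Rows that the tests of genes did not use also held values. MIR6723, a microRNA gene of 89 bp on chromosome 1 (hg19, 567705 to 567793), was listed at 13856200 FPKM in replicate 2 and was not among the names of the other libraries. Rows under 200 bp held 96.8% of the deposited FPKM of replicate 2, a share that rests largely on this 1 row. A value of this size in a row of 89 bp, listed in 1 library alone, is not read as a level of the microRNA. The row of the mitochondrial genome was at 2253 ± 37.6 FPKM (SD, n = 3). Loci without a gene name reached 1 FPKM or more in 3733, 4661 and 4617 cases in replicates 2, 3 and 4.

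Some genes were at 0 in 1 or 2 libraries and at 10 FPKM or more in another, 127 in all. They include the genes of the largest range between libraries: MIR4461 at 4631, 2347 and 0 FPKM in replicates 2, 3 and 4, HCG25 at 2303, 0 and 0, S100A3 at 2158, 0 and 0, MIR4737 at 0, 7.08 and 968, SNORD102 at 0, 0 and 1216, SNORD32A at 0, 0 and 1154, SNORD24 at 0, 0 and 1079, SNORA65 at 0, 0 and 1031, SNORD35B at 0, 0 and 1020.0 and SNORD16 at 0, 0 and 899 FPKM. In the libraries that listed them at 0, 57.5% (73 of 127) had an overlapping row of at least 0.5 times their value elsewhere, against 4.91% (271 of 5517) of genes of at least 10 FPKM in every library (Fisher's exact test, 2-sided, p = 1.71e-57). Of the 127 genes 70 are small RNA genes and 56.7% share a row, against 10.2% of tested genes, and genes on a shared row carry the value of that row. A gene's own row was never counted as overlapping. The shared row of a comparison gene was thus left out, while for a gene at 0 that row could count. The contrast is therefore partly built in for genes on shared rows, and with them for the 127 genes together. Among small RNA genes on shared rows the share was 79.1% (34 of 43) against 2.63% (2 of 76; Fisher's exact test, 2-sided, p = 4.26e-19). Among protein-coding genes with rows of their own it was 38.5% (10 of 26) against 5.06% (229 of 4530; Fisher's exact test, 2-sided, p = 3.31e-07). Small RNA genes with rows of their own had such a row in 19 of 27 cases, with only 1 gene to compare. Each gene was also compared with itself: 73 of 127 had such a row where they were at 0 and 37 where they were highest (exact McNemar test, 2-sided, p = 2.84e-10), but a shared row counts as the gene's own, which lowers the second count. Of 55 genes with rows of their own the counts were 30 and 25, and only 5 genes differed, too few for that test to pass. Among the 26 protein-coding genes with rows of their own, 10 had such a row where they were at 0 and 6 where they were highest. In these 6 the row was there in both cases, so its presence does not set apart the libraries at 0. Such a row was more common at 0 among these coding genes than among the comparison genes, but whether it took their reads stays open. In replicate 2 S100A3 carried the value of S100A4, with which it shared a row. S100A4 itself stayed at 2102 and 2147 FPKM in replicates 3 and 4. SNORD44 in replicate 3 (479 FPKM) and SNORD81 in replicate 4 (314 FPKM) carried the values of GAS5. The high values of these genes are those of a shared row and no level of the gene alone. Other genes on shared rows, and genes without an overlapping row, stay open. Replicate 2 stood alone in 38 of the genes (29.9%, exact 95% interval 22.1% to 38.7%), whereas the zeros parted replicates 3 and 4, which shared all but 1 of their gene names, in 89, so the annotation of replicate 2 cannot account for the pattern as a whole. It stays open for those 38.

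Of 38 rows of under 200 bp at 1000 FPKM or more in replicates 3 and 4, 35 had a value above their own deposited interval. The median ratio of FPKM to the middle of the interval was 210.4 in the 38 rows (lowest 0.570) and 0.988 in 118 longer rows of the same level, which is consistent with a length correction that inflates short rows. Of the longer rows 37 lay above and 32 below their interval, so the interval is no close guide there either. In replicate 2 the median ratio of short rows was 1, so their interval gives no hint there.

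Proliferation genes moved together between the libraries, with 15 of 20 highest in replicate 3 and 19 of 20 lower in replicate 4 than in replicate 3, and 19 lower than in replicate 2. The median difference of replicate 4 from the mean of the other libraries was -0.40 (log2, SD over genes 0.30), that of replicate 3 was 0.28 (SD over genes 0.22) and that of replicate 2 was 0.08 (SD over genes 0.22). Each difference contains the other libraries, so a low replicate 4 and a high replicate 3 are not fully told apart. Each sets 1 library against 2, in a list singled out after its values were seen, and cell cycle genes move together, so whether the cultures differ was not tested. The difference of replicate 3 fell with GC content across 9133 genes, which are not independent replicates (Spearman's rho -0.586), from 0.13 in the lowest of 5 equal bins of GC content to -0.27 in the highest. After the trend on GC content was removed the list median of replicate 3 was 0.29 (SD over genes 0.19), at the 100th percentile of 10000 random lists, and after the trend on transcript length it was 0.31, again at the 100th percentile. For replicate 4 it was -0.38 after the trend on GC content and -0.39 after that on length. The percentiles place the list among other genes and are no test between libraries. Removing each trend left the difference of replicate 3 nearly unchanged, which argues against both trends as its whole cause. For replicate 4 the same holds for the trend on GC content. Replicate 4 had almost no trend on length to remove (Spearman's rho 0.012), so its removal was no test of length there. A difference in the share of dividing cells between cultures or another batch difference stays open, as untested.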

How the results depend on the processing

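Leaving out the genes that share a row, and leaving out genes at 0 in 1 or 2 libraries and at 1 FPKM or more in another, were chosen after seeing the data, and the other alternatives before. No paired analysis was possible because there was 1 group. The number of genes called above ranged from 7379 (level of 5 FPKM) to 11719 (level of 0.5 FPKM) and stayed within 1.5 times the main count under every alternative. Genes called below fell to 2165 with genes under 0.1 FPKM in every library left out, which removes most of them by construction. Genes not called ranged from 2216 to 2530 when 1 library was left out, the highest without replicate 4, where fewer libraries enter the test. Lists below the background numbered 12 with the mean of the list, 12 with a pseudocount of 0.1 and the mean, 0 with all genes as background (permutation test, 2 at an unadjusted p under 0.05) and 18 with background genes of at least 0.1 FPKM, so this count depends on the background and the summary. With the mean, by either pseudocount, the lists that gained a call below were MSC exclusion markers, cardiac muscle, glia, endothelial, keratinocyte, melanocyte, immune, endoderm and liver, HOX and HLA class II. Lists above the background ranged from 5 (without genes on shared rows) to 10 (pseudocount of 0.1 and the mean), with 9 by the mean alone and 9 with all genes as background. The stromal matrix list exceeded each lineage list it was set against in all 119 recomputed differences. Of the recomputed list levels 296 kept their call or stayed uncalled, 46 gained a call and 7 lost it. The side of a level that stayed uncalled was not compared. Of the recomputed levels of named genes 1957 kept their call or stayed uncalled, 16 gained a call, 35 lost it and 31 changed side.

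Mean Pearson's r between libraries was 0.918 and Spearman's rho 0.928 over genes of mean FPKM of at least 1. When 1 library was left out, r ranged from 0.968 to 0.972 and rho from 0.956 to 0.958, and the median coefficient of variation from 6.75% (without replicate 3) to 9.31%. That coefficient was 8.71% over genes of at least 10 FPKM. Rescaling to TPM raised the median gene by 0.59 (log2), which lowers the level of detection by construction, and median-of-ratios factors moved it by less than 0.01.

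Changes of side that involved a call were as follows. At a level of 5 FPKM the difference from the level was -1.21 for ACTC1, -0.00096 for AGPAT2, -0.47 for FABP4, -0.86 for HOXA7, -0.29 for HOXC11, -0.96 for HOXC4, HOXC5 and HOXC6, -0.12 for HOXD10, -0.81 for HOXD8, -1.02 for HOXD9, -0.11 for MKI67, -0.96 for MSX2, -0.96 for PAX3, -0.41 for SNAP25 and -0.81 for SOX6, since the level is then above their mean on the log2(FPKM + 1) scale. At that level AFP, DNMT3B, EMCN, KRT15, MBP, MLANA and TNNT2 gained a call below (-2.11, -1.62, -1.71, -1.82, -1.59, -1.67 and -1.95), while COL7A1, KLF4, MATN3 and MYC lost their call (0.35, 0.28, 0.19 and 0.42). At 0.5 FPKM and after TPM rescaling it was 0.38 and 0.52 for DNMT3B, 0.29 and 0.40 for EMCN, and 0.41 and 0.55 for MBP. The abundant noncoding RNA list moved to -0.76 from its background without genes on shared rows, and the cause was not tested. When 1 library was left out the level of APOA1 ranged from -0.91 (without replicate 3) to 0.61, and those of HCG25 and S100A3 from -1 (without replicate 2) to 4.59 and 4.54. MIR4461 gained a call above without replicate 4 (10.69), the library that lists it at 0. Without replicate 4, the library that alone lists them above 0, the levels of SNORA65, SNORD102, SNORD16, SNORD24, SNORD32A and SNORD35B were -1, the lowest of ranges that reached 4.01, 4.12, 3.91, 4.04, 4.09 and 3.998. Since FPKM holds no counts, depth limits the precision of genes near the level by an amount that cannot be given.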

Other observations

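Noncoding RNAs were abundant in part. GAS5 (376 ± 90.2 FPKM), MEG3 (135 ± 30.1 FPKM) and NEAT1 (52.6 ± 2.71 FPKM) were highest in the abundant noncoding RNA list, each on a shared row, and H19, also on a shared row, was at 0.151 ± 0.0613 FPKM. Only 8 of the 11 genes fixed for this list were measured, so the highest genes and the list median hold for these 8 alone. Of them 5 were called above the level, 1 below and 2 were not called (5 and 1 above and below adjusted over the list alone). The median of 4.77 ± 0.10 (log2) lay above random lists (permutation adjusted p = 0.0466, 3 of 3 libraries), a call that ended without replicate 3 (difference 2.78), with the mean of the list (1.86), with a pseudocount of 0.1 and the mean (2.54) and with background genes of at least 0.1 FPKM (1.64). Leaving out genes on shared rows removes 5 of the 8 genes, among them the 3 highest and H19. The median of the rest lay below random lists (-0.76) and was not called.

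Histone genes of the replication clusters were split. H2BC12 (113 ± 37.9 FPKM), H2AC6 (54.6 ± 7.82 FPKM, on a shared row) and the linker histone H1-2 (43.2 ± 8.29 FPKM) were highest, and H1-4 was listed at 0, 0.0721 and 0.155 FPKM and H3C2 at 0, 0 and 0.159 FPKM. Of 12 genes 8 were called above and 4 below (8 and 4 adjusted over the list alone), and the median of 2.59 ± 0.17 (log2) was not separated from random lists (permutation adjusted p = 0.636).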
